A study of Mus musculus with 9 samples.

How the data were processed

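Total RNA from the livers of male mice 60 days old was made into stranded mRNA libraries and sequenced. The labels place 9 libraries in 3 groups of 3, namely wild type (WT), Snd1 knockout (KO) and a knock-in with a mutated Tudor domain (KI). Library names below join the group and the replicate number of the title, such as WT_1. The label for cell type reads hepatocyte, but the material described is liver tissue, so every cell of the organ can contribute transcripts.

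The authors deposited 1 table with a value for each of 19944 genes in each library, in a unit of signal, called normalized counts in its name. Per the submitters' processing notes, reads were aligned with TopHat2 and Bowtie2 to the mouse genome build GRCm38 and counted per gene with featureCounts. The notes give no versions, and they do not name the gene annotation, the strand setting, the filter on low counts or the scaling tool. Reads from overlapping genes on opposite strands, and reads shared by closely related gene copies, therefore carry an uncertainty of unknown size.

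Each deposited column was found to hold whole multiples of a single step per library, written to 2 decimals. The values are thus gene read counts that the authors divided by a size factor of 0.8921 to 1.1051, and whole reads could be recovered by undoing that division. With a tolerance of 0.0051 deposited units, at least 99.994% of the values in each library came out whole, and 5 values in all did not. The recovered totals run from 59678412 to 66384374 reads per library. At that depth counting error is small beside the spread between libraries of a group for well-expressed genes. No column of the table was left without a sample. Of the genes, 554 had no symbol, and 7 symbols occurred more than once, so genes were followed by identifier.

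The deposited values were tested as log2(value + 1), with the pseudocount of 1 included, in genes whose mean over the 9 libraries was at least 10, which left 15238 genes. The fit was made with limma 3.58.1 in R 4.3.3, using a trend of variance with abundance and 1 mean per group, so all 9 libraries share the estimate of the spread with 6 residual degrees of freedom. KO was compared with WT, KI with WT and KI with KO, all tests two-sided, with Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p under 0.05 were called higher or lower, with no minimum fold. Errors beside means are standard deviations over 3 libraries, and errors beside log2 fold changes are standard errors from the fit. The recovered reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0 as alternatives. Other computing used Python 3.11 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

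A collection of 46 gene lists was fixed before the data were examined, along with the tests, the alternatives and the rule for named genes. The lists cover liver pathways, protein complexes, markers of other cell types and signs of RNA quality. Each list with at least 5 tested members was tested with camera from limma at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation was the alternative, and fry gave a test of each list by itself. Members called are counted over all genes tested and also with p adjusted over the list alone.

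The named genes are Snd1, and per comparison the 10 called genes in each direction with the largest log2 fold change among genes with a mean of at least 50 whose groups do not overlap. For each list described they also include the called members, at most the 4 with the smallest adjusted p. A comparison with fewer than 5 genes called is described by the 5 smallest p in each direction, stated as not passing where they did not. Predicted genes with Gm or Rik numbers are counted but not named, and any gene named outside this rule is said to have been chosen after its values were seen.

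Both comparisons against WT use the same 3 WT libraries, which gives them a covariance even without any effect. It was estimated from 100 simulated draws of unchanged groups. In each draw the residuals of all 9 libraries were shuffled over the libraries with random signs and added to the WT mean of each gene. The simulated WT group can thus carry residuals of any genotype. The draws describe a shared control in general and not these 3 WT libraries. Genes within 10 Mb of Snd1, placed with GENCODE release M21 coordinates, were compared with all other genes by Fisher's exact test. The replicate numbers in the titles differ from those in the description fields, and the libraries were not treated as paired. Replicates were checked for duplication, and the closest pair within a group differed by a chi-square of 91.3 per degree of freedom, so no library repeats another.

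The procedure was tested on simulated data in which 200 genes per comparison were changed by 1.5, 2 or 4-fold between unchanged groups. For KO against WT, limma recovered 3% of the changes of 1.5-fold, 41.8% of those of 2-fold and 86.4% of those of 4-fold, with 4 false calls among 15047 genes. For KI against WT it recovered 6%, 37.3% and 84.8%, with 4 false calls, and for KI against KO 4.5%, 34.3% and 83.3%, with 3. DESeq2 recovered more at 2-fold (64.2%, 67.2% and 56.7%) with 53, 43 and 38 false calls. Changes of 1.5-fold in a single gene are thus mostly out of reach of this design. Each gene was drawn independently in the simulated data, with no deviation shared by the genes of a library. The false calls may therefore differ in the real libraries, where genes vary together.

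A total of 26 settings besides the one described were tried. They change the pseudocount to 0.5 or 5, the filter, the scaling, the libraries fitted together, the weights, the block, the minimum fold, the test and the camera correlation, and they leave out each library in turn. Of these, 3 settings concern pancreatic transcripts found in 3 libraries and were chosen after the data had been examined. They leave those libraries out, add the summed signal of the pancreas list as a covariate, or drop the genes that follow it, with a correlation above 0.9 and a level at least 8-fold higher in those libraries. Splicing, transcript isoforms and the mutated Tudor codons were not examined, because the table holds 1 value per gene.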

Results

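SND1 is a protein of nuclease-like repeats and a Tudor domain, a fold that binds methylated arginine. The labels describe livers from WT mice, from KO mice without Snd1 and from KI mice with a mutated Tudor domain, and they ask what the domain contributes to transcription. The titles name the FVB strain. Each genotype had 3 libraries, with recovered totals from 59678412 reads in KI_1 to 66384374 in KI_2. All p-values measure the spread between these 9 samples only, and the labels do not say whether litters or cages were shared.

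Snd1 lies on chromosome 6 from 28475139 to 28935162 on the forward strand of GRCm38 (gene ENSMUSG00000001424). Its normalized count was 6951, 8446 and 6512 in the WT libraries, 227, 414 and 359 in the KO libraries and 5373, 7941 and 5595 in the KI libraries. The means were 7303 ± 1014 in WT, 334 ± 96.2 in KO and 6303 ± 1423 in KI (SD, n = 3 each). Snd1 was 22.4-fold lower in KO than in WT, a log2 fold change of -4.48 ± 0.23 (SE, limma adjusted p = 8.82e-06). KI and WT were not distinguished (log2 fold change -0.23, adjusted p = 0.745), and KI exceeded KO by 4.26 on the log2 scale (adjusted p = 1.59e-05). The table has 1 value per gene, so it does not show which exons the KO reads came from or whether KI transcripts carry the mutation.

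**Figure D1:**
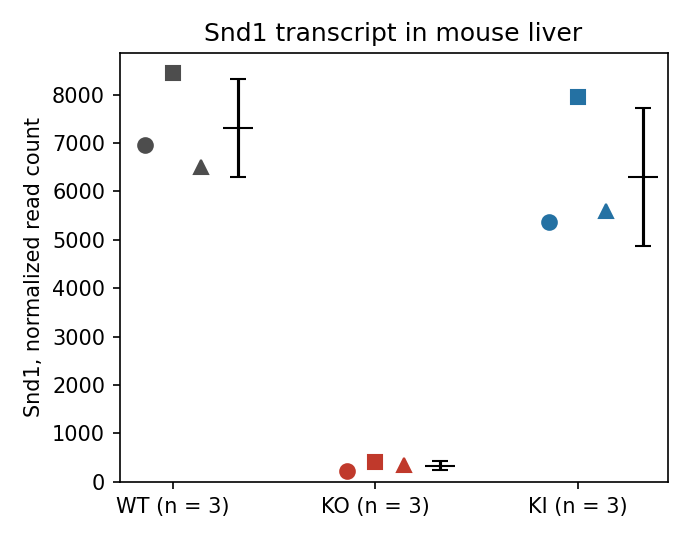
Snd1 transcript level in each library as normalized read count, with points for the 3 libraries of each genotype and, beside them, the mean with its SD. The KO libraries lie between 227 and 414, and every WT and KI library lies at or above 5373.

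Transcripts of the exocrine pancreas were present in 3 of the libraries. The fixed list of pancreas and gut markers took 5.13% of the reads in KI_3, 1.08% in WT_3 and 0.441% in KI_1, and between 0.00765% and 0.0112% in each of the other 6. Amylase (Amy2a5) reached 924072 normalized counts in KI_3, 200914 in WT_3 and 69867 in KI_1, and the digestive enzyme genes Ctrb1 and Pnlip followed the same order. These 3 genes were chosen after their values were seen. The first principal component carried 44.2% of the variance and placed these 3 libraries on one side. Of the 14 genes of the list limma called 0 in each of the 3 comparisons. Because the affected libraries are 1 of WT, 0 of KO and 2 of KI, counts without them stand beside each comparison.

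**Figure D2:**
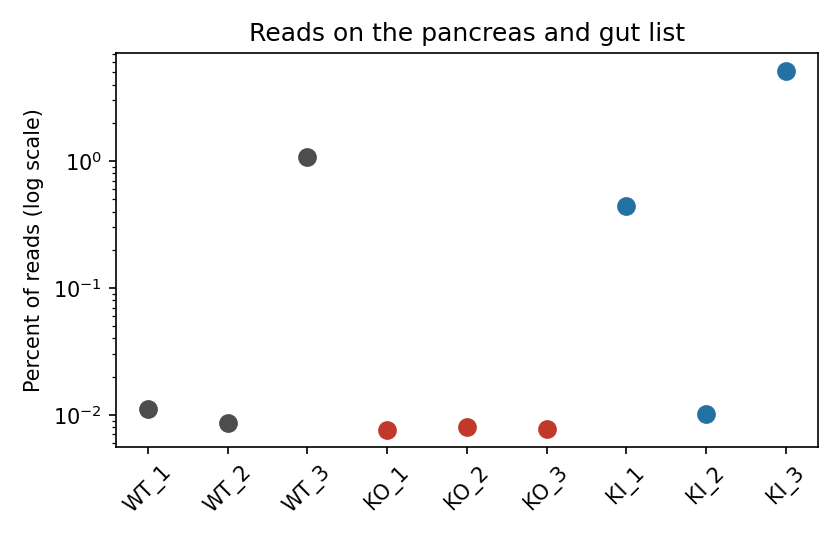
Percent of the reads of each library that fell on the list of pancreas and gut markers, on a log scale, with 1 point per library coloured by genotype. KI_3 (5.13%), WT_3 (1.08%) and KI_1 (0.441%) stand above the other 6, none of which passes 0.0112%.

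Loss of SND1 was examined by comparing KO with WT. The largest increases were in genes of the hepatic acute phase response, the set of secreted proteins made during inflammation. Serum amyloid A2 (Saa2) rose from 259 ± 10.8 in WT to 633599 ± 245337 in KO (SD, n = 3), a log2 fold change of 11.16 ± 0.32 (SE, adjusted p = 8.44e-08). Saa1 rose from 1691 ± 282 to 713292 ± 278051 (log2 fold change 8.64, adjusted p = 9.07e-07), though Saa1 and Saa2 are near copies and reads may be shared between them. The iron-chelator carrier Lcn2 rose from 245 ± 108 to 138309 ± 87664 (log2 fold change 8.92, adjusted p = 3.06e-05). Among the largest decreases were genes of drug metabolism. The methyltransferase gene Inmt fell from 23756 ± 969 to 551 ± 753 (log2 fold change -6.50, adjusted p = 0.0016), and the carboxylesterase gene Ces1d from 40873 ± 2095 to 2083 ± 3008 (log2 fold change -5.55, adjusted p = 0.0048).

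In this comparison limma called 706 genes higher and 640 lower among 15238 tested. Of these, 327 were at least 2-fold higher and 315 at least 2-fold lower. Groups did not overlap in 29.1% of the genes tested, where chance gives 10%. The other genes with the largest increases were Saa3 (166 to 110429), Orm2 (289 to 19260), the integrin gene Itga2 (13.3 to 678) and Prtn3, which encodes a neutrophil protease (5.21 to 403). A2m, Atp6v0a4 and Trat1 were close to 0 in WT, with means of 3.28, 1.28 and 1.61, and had means of 5507, 350.4 and 262 in KO. The other genes with the largest decreases were Cyp3a16, Cyp2a21-ps, Cyp2a4, Gsta2, Gsta5, Hamp2, Cyp2a5 and Ces1f, with log2 fold changes from -6.61 to -4.55. Cyp2a5, a coumarin hydroxylase, fell from 27708 ± 7188 to 2237 ± 2924. The Saa, Orm, Cyp2a, Cyp2c, Ces1 and Gsta families are made of similar copies, so the split of reads within each family is uncertain.

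The acute phase list had 23 of its 25 tested members higher in KO, none lower and 2 not called, and 24 were higher with p adjusted over the list alone. The median log2 fold change of the list was 2.99 (camera adjusted p = 3.88e-28, and adjusted p = 0.372 with an estimated correlation). Its genes took a mean of 16.2% of the reads in KO, 1.92% in WT and 1.79% in KI. In every KO library the mean log2 deviation of the list from the WT mean was raised, by 2.84, 4.28 and 4.21, while the WT and KI libraries lay between -0.19 and 0.18. Markers of neutrophils and monocytes had a median log2 fold change of 1.60 in KO and 1 of 11 members called, the collagenase gene Mmp8, which was 2.64 in WT and 89.4 in KO (list camera adjusted p = 0.0109, and adjusted p = 0.901 with an estimated correlation). Their mean log2 deviation from WT was 2.08 in KO_2 and 3.02 in KO_3, but 0.30 in KO_1, inside the WT range of -0.96 to 0.51, and 1.22 in KI_3. Among 16 markers of Kupffer cells and macrophages, 3 were higher in KO, namely Mpeg1 (3832 ± 905 to 9106 ± 1101), Marco and Cd163, and the list did not pass (camera adjusted p = 0.267).

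**Figure D3:**
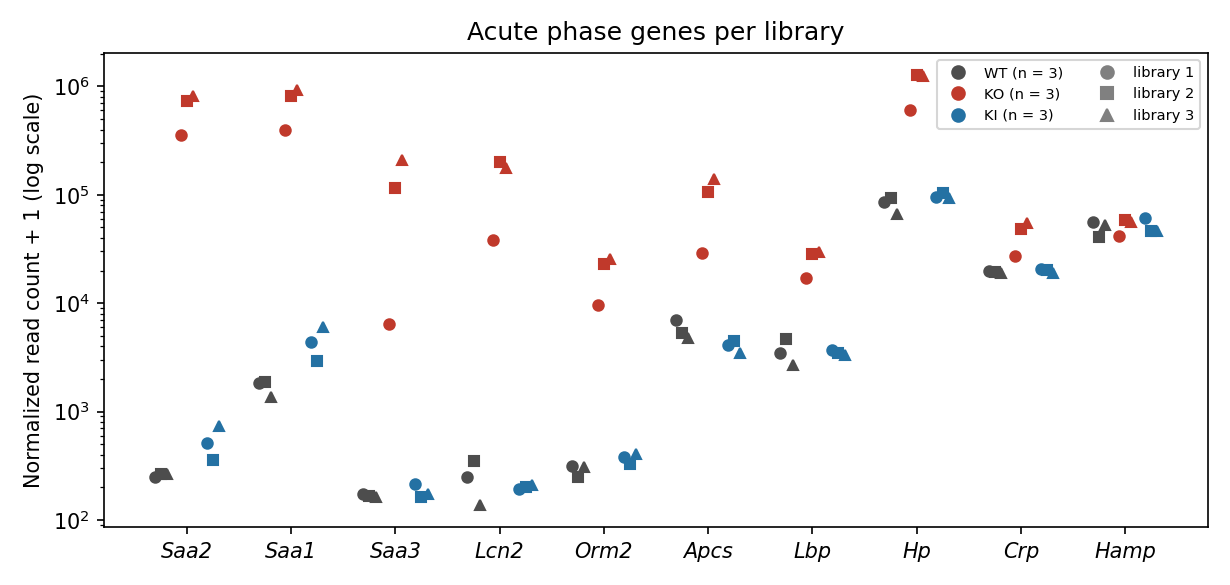
Normalized read count plus 1 on a log scale for 10 acute phase genes, chosen after their values were seen, with 1 point per library, colour for genotype and marker shape for library. Saa2 lies between 353401 and 809849 in KO and at or below 739 in every WT and KI library, while Hamp shows no separation of the groups.

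Xenobiotic metabolism moved the other way in KO. Of the 28 genes of the list 17 were lower, 1 was higher and 10 were not called, and 20 were lower with p adjusted over the list alone. The cytochrome P450 genes Cyp2c37, Cyp2c54 and Cyp2c50 fell, with log2 fold changes of -3.89, -3.99 and -3.80 and adjusted p of 3.05e-04, 3.17e-04 and 6.05e-04. Cyp3a13, chosen after its values were seen, was the member that rose, from 2251 ± 365 to 8652 ± 2893. The list had a median log2 fold change of -1.61 (camera adjusted p = 2.09e-13, and adjusted p = 0.658 with an estimated correlation). Of 21 genes of bile acid synthesis and transport 6 fell, among them Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 10223 ± 3404 to 910 ± 676 (log2 fold change -3.96, adjusted p = 0.00822), and Cyp8b1, the sterol 12-alpha-hydroxylase, from 16340 ± 2373 to 8530 ± 2184 (adjusted p = 0.0161). With p adjusted over that list alone, 11 were lower and 1 was higher, with a list median of -0.61 (camera adjusted p = 2e-04, and adjusted p = 0.848 with an estimated correlation). The mean log2 deviation of the bile acid list from WT was -0.13 in KO_1, -0.72 in KO_2 and -1.06 in KO_3. The WT libraries lay between -0.1 and 0.12, so KO_1 was close to them. Of 28 targets of the fatty acid receptor PPAR-alpha 8 were lower and 0 higher, with log2 fold changes of -1.96 for Ehhadh, -2.68 for Acot1 and -2.87 for Acaa1b, and Cyp4a10 at 2708 in WT and 181 in KO. Over that list alone 13 were lower and 4 higher, and its median was -0.36 (camera adjusted p = 3.78e-04, and adjusted p = 0.848 with an estimated correlation).

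Genes of the circadian clock split into opposite directions in KO. Of 21 tested, 4 were higher and 9 lower, with 4 higher and 12 lower when p was adjusted over the list alone. Arntl, which encodes the core activator BMAL1, rose from 130 ± 38.7 to 555 ± 175 (log2 fold change 2.09, adjusted p = 0.00262). Wee1, a kinase gene under clock control, fell from 1214 ± 74.6 to 110 ± 65.5 (log2 fold change -3.70, adjusted p = 0.00134), and Per3 from 1842 ± 155 to 454 ± 220 (adjusted p = 0.00468). The list median was -0.65 (camera adjusted p = 0.00135, and adjusted p = 0.848 with an estimated correlation). Levels of clock genes change over the day, and the sample details used here hold no time of collection. A difference in sampling time between the groups was therefore not examined and cannot be told apart from the genotype.

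**Figure D4:**
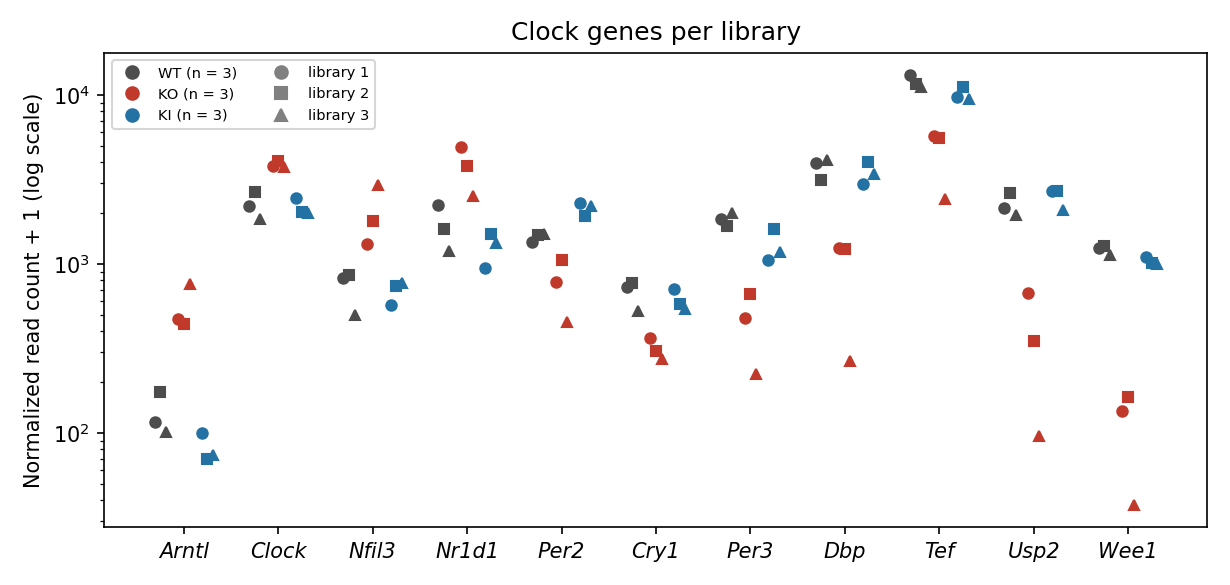
Normalized read count plus 1 on a log scale for 11 clock genes, chosen after their values were seen, with 1 point per library, colour for genotype and marker shape for library. Arntl lies between 438 and 756 in KO and at or below 173 elsewhere, and Wee1 between 36.2 and 161 in KO and at or above 992 elsewhere.

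Genes with a known bias between the sexes also moved in these male KO livers. Of 20 female-biased genes 7 were lower and 1 higher, with 9 lower and 2 higher over the list alone. Cyp2c39 fell from 8448 ± 1367 to 1852 ± 595 (log2 fold change -2.23, adjusted p = 4.62e-04), Rdh16 and Cyp3a44 fell as well, and Cyp17a1, a steroid hydroxylase, rose from 135 ± 4.02 to 498 ± 211 (adjusted p = 0.00915). The list median was -1.09 (camera adjusted p = 2e-04, and adjusted p = 0.372 with an estimated correlation). Of 21 male-biased genes 3 were lower, Cyp4a12b, Cyp4a12a and Selenbp2, with a list median of -0.64 (camera adjusted p = 0.00517, and adjusted p = 0.939 with an estimated correlation). Over that list alone 7 were lower and 1 higher. The KO libraries did not agree, with mean log2 deviations of the list of 0.35 in KO_1, above every WT library (-0.12 to 0.13), and -1.21 and -1.04 in KO_2 and KO_3. The median ran from -1.06 to -0.39 over the settings tried.

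Other shifts in KO involved energy and growth. Of 24 nuclear genes of oxidative phosphorylation 2 fell, the complex I subunit gene Ndufb9 and the succinate dehydrogenase gene Sdhb, with log2 fold changes of -0.49 and -0.95, and 9 were lower over the list alone (median -0.37, camera adjusted p = 1.56e-06, and adjusted p = 0.848 with an estimated correlation). The mean log2 deviation of this list from WT was -0.1 in KO_1, -0.43 in KO_2 and -0.56 in KO_3. Of 26 cell cycle genes 2 fell, the replication clamp gene Pcna and the transcription factor gene E2f1, and 5 were lower over the list alone (median -0.86, camera adjusted p = 2e-04, and adjusted p = 0.392 with an estimated correlation). Of 20 pericentral hepatocyte genes 3 were lower and 1 higher (median -0.63, camera adjusted p = 0.00377, and adjusted p = 0.901 with an estimated correlation), with KO_1 at -0.05 inside the WT range of -0.17 to 0.17. Heat shock genes went both ways, with 4 of 15 lower, among them the chaperone genes Hspa8 (43051 ± 2398 to 21857 ± 1661), Dnaja1 and Hsph1, and 3 higher, among them Hspa1b (118 ± 23.9 to 334 ± 14.9). That list did not pass (camera adjusted p = 0.0628). In all 17 of 46 lists passed in KO against WT at the preset correlation, and 0 with an estimated correlation. By fry only the acute phase, female-biased, cell cycle and xenobiotic lists passed (fry adjusted p = 0.00196, 0.0135, 0.0245 and 0.0349).

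The number of genes called in KO depended on which libraries were fitted. It was 21 higher and 9 lower without the 3 libraries that hold pancreatic transcripts, with 29 of these 30 shared with the full count, and 511 higher and 443 lower with the pancreas covariate, with 891 of these 954 shared. Single libraries moved it to 1104 and 1412 without KO_1, 266 and 235 without KO_2, 447 and 331 without KO_3, 300 and 233 without WT_1, 372 and 239 without WT_2 and 345 and 264 without WT_3. DESeq2 called 1208 higher and 1087 lower and shared 1330 genes with limma, while edgeR called 1210 in all and shared 1155.

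The contribution of the Tudor domain was examined by comparing KI with WT. In total limma called 4 genes, all listed here. The chaperone gene Hsph1 rose from 3831 ± 206 to 7070 ± 747 (SD, n = 3), a log2 fold change of 0.88 ± 0.11 (SE, adjusted p = 0.0398), with every KI library (7848, 6359 and 7003) above every WT library. The cytochrome gene Cyp2c39 fell from 8448 ± 1367 to 2561 ± 295 (log2 fold change -1.72, adjusted p = 0.0398). The other two called genes, named after their values were seen, both fell: Gm4366, annotated as a processed pseudogene, from 645 ± 55.4 to 177 ± 21.0 (adjusted p = 0.0208), and Gm11437, annotated as protein coding, from 335 ± 58.5 to 92.1 ± 20.8 (adjusted p = 0.0398).

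The genes with the next smallest p in KI against WT did not pass. Chordc1, which encodes a partner of the chaperone HSP90, had means of 2095 in WT and 3727 in KI (log2 fold change 0.83, adjusted p = 0.0557). Atp11a was at 557 and 1395, Etfbkmt at 3397 and 6863, and Slc41a2 at 698 and 1787, with adjusted p of 0.0817, 0.085 and 0.085. On the lower side Cyp2c38 was at 2296 in WT and 651 in KI, the water channel gene Aqp4 at 684 and 183, Cyp8b1 at 16340 and 6266 and the checkpoint kinase gene Atr at 1023 and 606, with adjusted p of 0.0532, 0.0532, 0.0557 and 0.0557. This comparison had 1 gene higher and 3 lower by limma, with 1769 at an unadjusted p under 0.05, and groups did not overlap in 19.6% of the genes, where chance gives 10%. edgeR called 1 gene, shared with limma, and DESeq2 called 372, which include the 4.

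Among the lists that passed in KI, the heat shock list had the largest median. All 15 of its members had positive log2 fold changes, 1 of them called over all genes and 11 higher with p adjusted over the list alone, at a median of 0.74 (camera adjusted p = 5.15e-15, and adjusted p = 0.0899 with an estimated correlation). Values for members that did not pass over all genes, chosen after they were seen, include Hspa8 with means of 43051 in WT and 71421 in KI, Hsp90aa1 with 20763 and 36701, and Dnajb1 with 1045 and 1747. The mean log2 deviation of the list from WT was 0.85, 0.62 and 0.73 in the KI libraries and between -0.05 and 0.08 in the WT libraries, so it was raised in the KI library without pancreatic transcripts too. The list of MYC targets and ribosome biogenesis had 0 of 26 members called over all genes and 9 higher over the list alone, at a median of 0.28 (camera adjusted p = 3.03e-09, and adjusted p = 0.0899 with an estimated correlation). Nop58, a nucleolar protein gene chosen after its values were seen, was at 738 in WT and 1503 in KI, and its adjusted p was 0.0913.

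Several metabolic lists had negative medians in KI. The 13 mitochondrially encoded genes, a sign of RNA quality, were lower as well, with 0 called and a median of -0.27 (camera adjusted p = 0.00192, and adjusted p = 0.933 with an estimated correlation). Their mean log2 deviation from WT was -0.52 in KI_1, -0.16 in KI_2 and -0.24 in KI_3, and between -0.16 and 0.15 in the WT libraries. Of 20 genes of fatty acid and triglyceride synthesis 0 were called over all genes, with 6 lower and 1 higher over the list alone, at a median of -0.67 (camera adjusted p = 1.11e-04, and adjusted p = 0.933 with an estimated correlation). Its mean log2 deviation from WT was -0.75 and -0.70 in KI_1 and KI_3, which hold pancreatic transcripts, and -0.16 in KI_2, and without the 3 libraries with such transcripts the median was -0.24 and did not pass (camera adjusted p = 0.356), while with the pancreas covariate it was -0.53 (camera adjusted p = 0.000943). The desaturase gene Scd1, chosen after its values were seen, was at 175430 ± 28012 in WT and 54532 ± 32842 in KI, with an adjusted p of 0.162. The cholesterol synthesis list had 0 of 25 members called and a median of -0.40 (camera adjusted p = 3.3e-04, and adjusted p = 0.933 with an estimated correlation), and its median was 0.16 without the 3 libraries with pancreatic transcripts. The female-biased list had 1 member called, Cyp2c39, and 2 lower over the list alone, at a median of -0.50 (camera adjusted p = 7.47e-05, and adjusted p = 0.18 with an estimated correlation). Its median was -0.26 without the 3 libraries with pancreatic transcripts, where it did not pass, and -0.51 with the pancreas covariate, where it did (camera adjusted p = 1.33e-04 with the covariate). The acute phase list did not pass in KI, with a median of 0.02, 0 of 25 members called by limma and a camera adjusted p of 0.587. The list of arginine methyltransferases and Tudor readers had 0 of 21 members called and a median of 0.17 (camera adjusted p = 0.0175, and adjusted p = 0.475 with an estimated correlation). Its median was 0.06 without the 3 libraries with pancreatic transcripts and 0.15 with the pancreas covariate, and it did not pass in 5 of the 26 settings. In all 15 lists passed in KI against WT, and 0 with an estimated correlation. By fry only heat shock and MYC targets passed (fry adjusted p = 0.00319 and 0.0117). By camera, heat shock, MYC targets and spliceosome core each failed in 1 of the 26 settings, and every other of the 15 lists in 2 to 5. Without the 3 libraries with pancreatic transcripts, which leaves 1 KI library, most of the negative medians were smaller in size. The lists with negative medians no longer passed in that fit. The bile acid list was then at -0.19, where it was -0.37, and the PPAR-alpha list at -0.08, where it was -0.18.

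**Figure D5:**
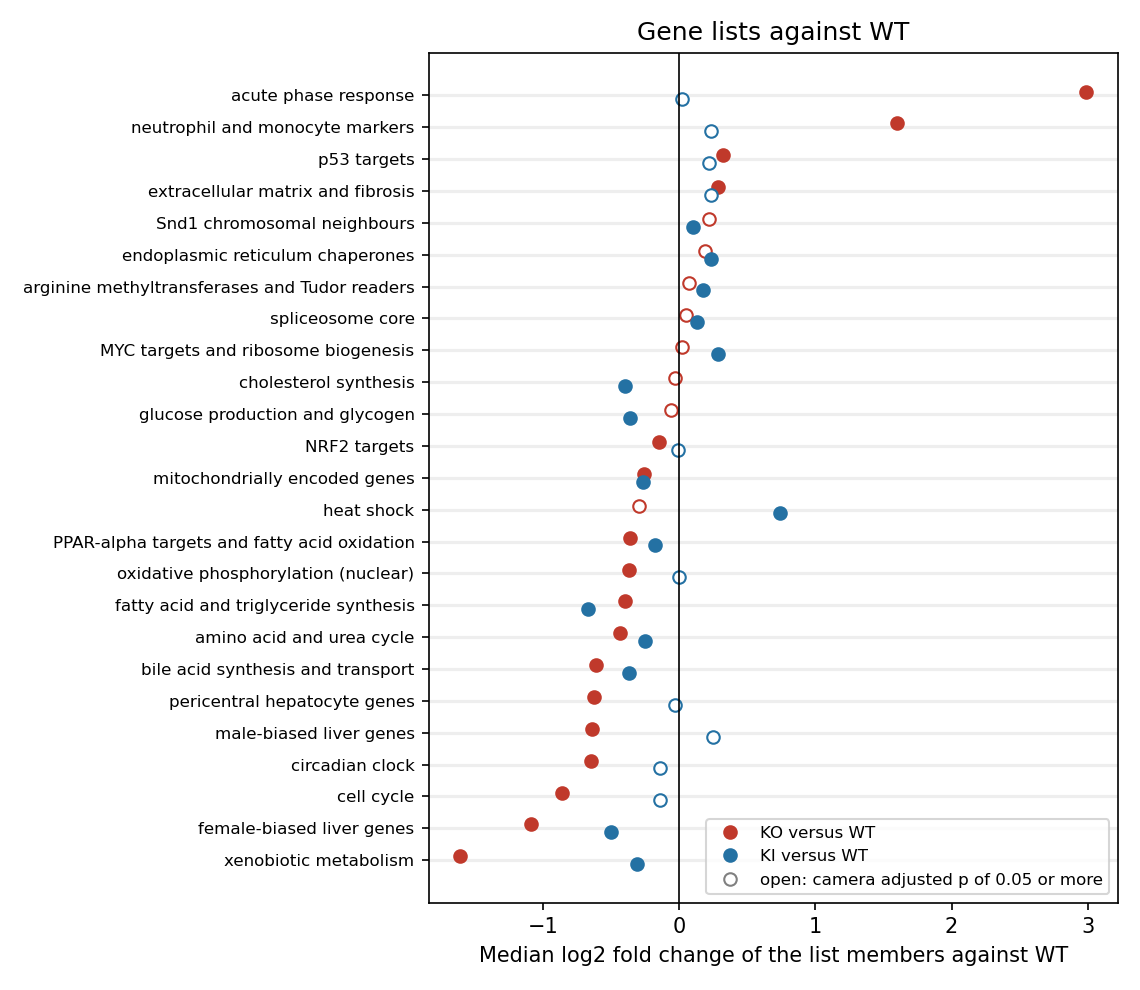
Median log2 fold change against WT of the 25 gene lists that passed in at least 1 comparison, the pancreas and gut list left out, with red points for KO and blue points for KI, and open points where the camera adjusted p was 0.05 or more. Filled points number 17 for KO and 15 for KI, with the acute phase list at 2.99 in KO and 0.02 in KI and the heat shock list at -0.30 in KO and 0.74 in KI.

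The KI calls depended on the libraries fitted, while the fold changes of the called genes did not change much. With the pancreas covariate limma called 0 genes, but Hsph1 had a log2 fold change of 0.837 ± 0.119 (SE) where the fit without it gave 0.88 ± 0.11, and Cyp2c39 had -1.61 ± 0.217 where it gave -1.72 ± 0.213 (adjusted p = 0.0881 for both with the covariate). These calls ended at the threshold, with nearly the same fold and 1 residual degree of freedom fewer. Without the 3 libraries with pancreatic transcripts, which leaves 1 KI library, limma called 0 genes, with Hsph1 at 0.762 ± 0.152 and Cyp2c39 at -1.65 ± 0.368. Likewise 0 were called without WT_1, WT_2, WT_3, KI_1 or KI_3, while 6 higher and 27 lower were called without KI_2, 12 and 23 without KO_1, 0 and 2 without KO_2 and 0 and 3 without KO_3. The heat shock list kept a median between 0.61 and 0.80 under every setting tried and passed in each except camera with an estimated correlation.

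The mutated domain was also compared with the absence of the protein, as KI against KO. The called genes with the largest differences were again acute phase genes. Saa2 was 633599 ± 245337 in KO and 536 ± 192 in KI (SD, n = 3), a log2 fold change of -10.18 ± 0.32 (SE, adjusted p = 2.14e-07), and Lcn2 was 138309 ± 87664 and 201 ± 9.39 (log2 fold change -9.10, adjusted p = 3.4e-05). Inmt was 551 ± 753 in KO and 16397 ± 3614 in KI (log2 fold change 5.95, adjusted p = 0.00265). The bile acid enzyme gene Cyp7a1 was 910 ± 676 and 10818 ± 4065 (log2 fold change 4.03, adjusted p = 0.00812).

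In KI against KO limma called 548 genes higher and 739 lower, of which 277 and 340 differed by at least 2-fold, and groups did not overlap in 26.4% of the genes, where chance gives 10%. Of the 1346 genes called in KO against WT, 740 were also called in KI against KO. The lower genes with the largest differences further include Saa1, Saa3, Orm2, the metallothionein gene Mt2 (45881 to 1187), the citrate transporter gene Slc13a5 (2438 to 56.6) and Prtn3. The higher genes include Cyp2a21-ps, Cyp3a61-ps1, Ces1d, Ces2b, Cyp2a4, Cyp2a5, Clec2h, Kcnk1 and Moxd1. Moxd1 had values of 1720, 65.8 and 2359 in KI_1, KI_2 and KI_3, so its level was high in the KI libraries that hold pancreatic transcripts, while WT_3, which also holds them, had 22.0.

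By list, 22 of 25 acute phase genes were lower in KI than in KO and 0 higher, with 24 lower over the list alone (median -2.85, camera adjusted p = 1.19e-27, and adjusted p = 0.257 with an estimated correlation). Of 15 heat shock genes 10 were higher, among them Hspa8 (21857 ± 1661 to 71421 ± 3981, adjusted p = 2.02e-04), Hsph1 (2600 ± 179 to 7070 ± 747, adjusted p = 1.47e-04), Hsp90aa1 and Chordc1, and 10 were higher over the list alone (median 0.89, camera adjusted p = 8.88e-10, and adjusted p = 0.257 with an estimated correlation). Of 28 xenobiotic genes 10 were higher and 1 lower, with 19 higher and 1 lower over the list alone (median 1.08, camera adjusted p = 3.27e-09, and adjusted p = 0.788 with an estimated correlation). Of 21 clock genes 9 were higher and 4 lower, with Arntl at 555 ± 175 in KO and 80.3 ± 16.0 in KI (adjusted p = 7.6e-04), and 10 higher and 5 lower over the list alone (median 0.44, camera adjusted p = 0.0293, and adjusted p = 0.947 with an estimated correlation). Of 26 MYC and ribosome biogenesis genes 4 were higher, among them the polyamine synthesis genes Odc1 and Srm, and 1, Ldha, was lower, with 11 higher and 1 lower over the list alone (median 0.43, camera adjusted p = 1.19e-05, and adjusted p = 0.257 with an estimated correlation). Of 21 male-biased genes 4 were higher, although KO_1 (0.35) lay inside the KI range of list deviations (0.26 to 0.68), led by Selenbp2 (1898 ± 1268 to 15222 ± 5247, adjusted p = 0.00233), and 9 were higher over the list alone (median 0.84, camera adjusted p = 2.57e-05, and adjusted p = 0.947 with an estimated correlation). Of 25 cholesterol synthesis genes 3 were lower, among them Hmgcs1, with the same 3 over the list alone (median -0.36, camera adjusted p = 0.0363, and adjusted p = 0.947 with an estimated correlation), and the median was 0.22 without the 3 libraries with pancreatic transcripts. In all 12 lists passed in KI against KO, and 0 with an estimated correlation. By fry only the heat shock, acute phase, MYC and cell cycle lists passed (fry adjusted p = 0.000387, 0.00112, 0.00856 and 0.0494).

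Counts in KI against KO moved with the libraries as well, to 0 higher and 4 lower without the 3 libraries with pancreatic transcripts, 85 and 142 with the pancreas covariate, 160 and 240 without KO_2, 182 and 299 without KI_1, 207 and 328 without KI_3, 293 and 523 without KO_3, 336 and 497 without WT_1 and 1235 and 1066 without KO_1. DESeq2 called 1010 higher and 1277 lower and shared 1272 genes with limma, and edgeR called 1200 in all and shared 1131.

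Genes changed in both KO and KI against WT were counted to see how far the mutated domain resembles the loss of the protein. Both comparisons called Cyp2c39 and Gm4366 lower, 2 genes where independence gives 0.126, and 0 higher genes were shared where independence gives 0.0463. Simulated unchanged groups with a shared simulated control had in common a median of 0 genes, with a mean of 9.43 and a range of 0 to 943 over 100 draws. Residuals in these draws came from libraries of every genotype, so they do not give the part due to these 3 WT libraries. The highest draw accounts for that mean, so the overlap of 2 lies above most draws. The range alone therefore does not place the overlap within what shared controls give. The same sign in both comparisons was found for 62.7% of all genes, where the simulated draws gave a median of 66.6% (from 34.3% to 86.9%). For the 1346 genes called in KO the median KI log2 fold change was 0.17 for those higher in KO and -0.23 for those lower, against 0.94 and -0.98 in KO itself, and the part of it that comes from shared WT libraries was not estimated. Across all genes the log2 fold changes of KO and KI correlated at 0.141 with a covariance of 0.061, while the simulated draws gave a median correlation of 0.452 (from -0.513 to 0.923) and a mean covariance of 0.113. The observed covariance was thus below that of unchanged groups, by a difference of -0.0524, and within their range of -0.0848 to 0.446. Genes are not independent replicates, and 3 WT libraries are too few to give each comparison its own controls.

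Genes around Snd1 were examined because an engineered allele carries linked sequence. Of the 79 tested genes within 10 Mb, 9 were called in KO against WT (11.4%, against 8.8% elsewhere), an odds ratio of 1.33 (95% interval 0.583 to 2.68, Fisher's exact p = 0.423). In KI against KO 9 were called (odds ratio 1.40, exact p = 0.311), and in KI against WT limma called 0. From the fixed list of 16 tested neighbours, Calu, a calcium-binding protein gene, rose from 7687 ± 462 in WT to 17907 ± 4410 in KO (adjusted p = 0.00304), and Grm8 was at 9.04 ± 9.71 and 61.4 ± 14.2 (adjusted p = 0.0197). The list gave 2 of 16 called in KO (exact p = 0.647) and 3 in KI against KO, with the interferon regulatory factor gene Irf5 as the third (exact p = 0.147). In KI against WT 14 of the 16 had positive log2 fold changes, with 2 higher over the list alone and a median of 0.10. There the list passed by camera (adjusted p = 0.03, and adjusted p = 0.475 with an estimated correlation). It did not pass in KO against WT (camera adjusted p = 0.157) or in KI against KO (camera adjusted p = 0.969). Atp6v0a4 and Akr1d1, named above or in the bile acid list, also lie within 10 Mb of Snd1.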

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

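The splits of the libraries were planned before the data were examined, while the tests that weigh the pancreatic transcripts and the acute phase genes were chosen after those results had been seen.

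Gene lists stand out here where the change from WT in KO and the change from WT in KI differed by the direct camera test of KI against KO. The median log2 differences of KI from KO were -2.85 for the acute phase list, -0.36 for cholesterol synthesis and -0.60 for neutrophil and monocyte markers. Positive medians were found for heat shock (0.89), xenobiotic metabolism (1.08), male-biased liver genes (0.84), pericentral hepatocyte genes (0.57), cell cycle (0.47), the circadian clock (0.44), MYC targets and ribosome biogenesis (0.43) and oxidative phosphorylation (0.36). Pancreas and gut markers had a median of 9.72 with 0 of 14 members called. Hsph1, Hspa8 and Dnaja1 of the heat shock list were lower in KO than in WT, and Hsph1 was higher in KI than in WT, so this gene was called in opposite directions. None of these 12 lists passed with an estimated correlation. Without KO_3 the median of the neutrophil and monocyte list was 0.0304, and without the 3 libraries with pancreatic transcripts that of the cholesterol list was 0.216.

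Other ways of dividing the libraries were counted for each comparison. For KO against WT, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 1346 genes, and the highest other split gave 0. For KI against KO it was 1 of 10, with 1287 genes in the real split and 0 in the highest other. For KI against WT 2 of the 10 splits gave at least the real count of 4, and the highest other gave 52. That split sets WT_1, WT_2 and KI_2 against WT_3, KI_1 and KI_3, which are the libraries with pancreatic transcripts, so it points to a structure of the samples. With the pancreas covariate the real comparison called 0 genes, but Hsph1 kept a log2 fold change of 0.837 ± 0.119 (SE) beside 0.88 ± 0.11 without it, so the lost calls do not show pancreatic transcripts as the source of the 4. With 10 splits a share under 0.05 is out of reach in all 3 comparisons.

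Pancreatic transcripts took 1.079% of the reads in WT_3, 0.4406% in KI_1 and 5.127% in KI_3, while the other 6 libraries held at most 0.0112%. Across the 14 genes of the list, of which Cela1, Fabp2 and Lgals4, named like Amy2a5 after their values were seen, are also measurable in the other libraries, the log2 excess in KI_3 and WT_3 correlated at 0.936. The log2 ratio of KI_3 to WT_3 had a median of 2.62 and an SD of 2.2 over these genes. Part of that SD comes from Lgals4, at 138 in KI_3 and 176 in WT_3. Its mean in the other 6 libraries was 143, so its excess in KI_3 was set to a floor. Every other gene of the list was higher in KI_3 than in WT_3. The SD therefore does not tell whether the enzyme genes stand in a fixed ratio, and the correlation alone does not show it. Pancreatic RNA mixed into the liver RNA may be the source, with Amy2a5 as the most abundant gene, but the correlation does not settle it. The tables argue against the KI allele as the cause, since the lowest KI share was 0.00934 of the highest WT share. When in collection or handling such a mixture could have arisen is not recorded in the labels.

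The acute phase genes of KO form the second pattern. Leukocytes in the KO livers are argued against as its whole source, because the summed rise of their markers was 0.012% of the summed rise of the acute phase list. The scaling by the authors is argued against as well, since the list median stayed at 2.96 under quantile scaling, where it was 2.99 before. The lowest list score of a KO library lay 2.66 above the highest WT or KI score, which loss of SND1 and an inflamed state shared by these KO animals for another reason would both give. These cannot be told apart, because every KO library has both and the labels record no health status, litter or cage.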

How the results depend on the processing

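The alternatives were fixed before the data were examined, except the 3 settings on pancreatic transcripts and their values, which were chosen after seeing the data. Snd1 stayed lower in KO than in WT past the threshold under every setting tried. Among single named genes, 4267 results stayed on their side of the threshold, 1102 lost the call with direction kept, 50 gained it and 0 changed direction. For gene lists 964 stayed, 129 lost the call and 6 changed direction. Rescaling by median of ratios moved nothing and says nothing about stability, and quantile scaling shifted the median gene by -0.008, -0.013 and -0.005 in the 3 comparisons. Depth ran from 59678412 to 66384374 reads and was not varied. Where no reason is given below, the cause was not tested.

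Without a filter KI against WT had 2 higher and 6 lower genes, an overlap with KO of 6, a covariance of 0.1566 and a correlation of 0.2637. With a mean of at least 50 it had 6 lower, an overlap of 5, a covariance of 0.02048 and a correlation of 0.06082. Fits of only the 2 groups compared have fewer libraries and gave 376 lower in KO, 12 higher and 16 lower in KI against WT, 220 higher and 388 lower in KI against KO, and an overlap of 16. Array weights gave 1547 and 1537 in KO, 57 and 94 in KI against WT, 1122 and 1319 in KI against KO, and an overlap of 75. A minimum fold of 2, which removes genes by construction, left 327 and 315 in KO, 0 higher in KI against WT and 277 and 340 in KI against KO. With camera at an estimated correlation 0, 0 and 0 lists passed.

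Replicate numbers do not pair the libraries. By title number the 9 pairs correlated between -0.136 and 0.568 with 3 over 0.1. Each library was matched to each other group, and in 9 of these 18 matches the best partner had the library's own number. By description number the range was -0.152 to 0.568, again with 3 pairs and 9 of 18. With the title number as a block KI against WT had 0 higher genes, and with the description number as a block 3 higher and 5 lower and an overlap of 5.

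On the recovered reads edgeR gave 0 higher and 1 lower in KI against WT, an overlap of 1, a covariance of 0.02051 and a correlation of 0.03473. DESeq2 gave 1208 and 1087 in KO, 163 and 209 in KI against WT, 1010 and 1277 in KI against KO and an overlap of 147, and turned the covariance to -0.03181 and the correlation to -0.03828. DESeq2 also made 53, 43 and 38 false calls on simulated data, in which genes were drawn independently.

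Without the 3 libraries with pancreatic transcripts, 2 WT, 3 KO and 1 KI library remain, and the lone KI library is assumed to vary like the other groups. This left 21 and 9 in KO, 0 and 0 with 8 lists in KI against WT, and 0 and 4 with 20 lists in KI against KO. Snd1 in KI against KO was 4.614 with an adjusted p of 0.0504 (1.59e-05 with all libraries), and the overlap was 0, the covariance 0.1294 and the correlation 0.2998. The pancreas covariate gave 0 and 0 in KI against WT, 85 and 142 with 20 lists in KI against KO, an overlap of 0, a covariance of 0.1139 and a correlation of 0.3138. Without the genes that follow the pancreatic transcripts KI against WT had 5 lower, an overlap of 4, a covariance of 0.1194 and a correlation of 0.3301.

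List medians that changed direction were NRF2 targets in KO (0.05602 under quantile scaling), neutrophil and monocyte markers in KI against KO (-1.223 to 0.03043 leaving out each library in turn, the highest without KO_3), cholesterol synthesis without the 3 libraries (0.1606 in KI against WT and 0.2162 in KI against KO), and pancreas and gut markers in KI against KO (0 without the 3 libraries and -0.2167 with the covariate).

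Leaving out each library in turn gave 266 to 1104 higher and 233 to 1412 lower in KO with 11 to 19 lists, 0 to 12 higher and 0 to 27 lower in KI against WT with 11 to 20 lists, and 160 to 1235 higher and 240 to 1066 lower in KI against KO with 10 to 15 lists. The overlap ran from 0 to 21, the covariance from 0.01065 to 0.1478 and the correlation from 0.01736 to 0.2698. The odds ratio near Snd1 ran from 0.3766 to 1.995 in KO, with a Fisher exact p of 0.0492 without KI_1, and from 1.007 to 1.96 in KI against KO. Snd1 ran from -4.662 to -4.23 in KO, from -0.4046 to -0.1171 in KI against WT and from 4.004 to 4.436 in KI against KO.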

Other observations

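Rpl7a and the tests of its copies below were chosen after the result had been seen, and the gene lists were fixed before the data were examined.

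Several groups beyond those described above moved in KO against WT. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 67.1 ± 37.5 to 1162 ± 615 (SD, n = 3, limma adjusted p = 0.00134), and the p53 target list had 2 of 18 members higher, the other being Trp53inp1 (median 0.32, camera adjusted p = 0.0163, and adjusted p = 0.848 with an estimated correlation). The matrix genes Lum and Fn1 rose, Fn1 from 63061 to 164440, and Timp1 was at 1.31 in WT and 72.3 in KO, with 3 of 23 members of the list of extracellular matrix and fibrosis higher (camera adjusted p = 0.0477, and adjusted p = 0.976 with an estimated correlation). Of 20 NRF2 targets 5 fell, among them the epoxide hydrolase gene Ephx1 from 15526 to 5818, and 1 rose (median -0.15, camera adjusted p = 0.0477, and adjusted p = 0.901 with an estimated correlation). The 13 mitochondrially encoded genes had 0 called by limma and a median of -0.26 (camera adjusted p = 0.0477, and adjusted p = 0.908 with an estimated correlation). These last 3 lists lay near the threshold. The matrix list did not pass in 9 of the 26 settings, the NRF2 list in 12 and the mitochondrial list in 8. The urea cycle gene Otc and the glycine methyltransferase gene Gnmt fell, with 2 of 31 amino acid genes lower and 1, Sdsl, higher (camera adjusted p = 0.0109, and adjusted p = 0.98 with an estimated correlation). Of 20 genes of fatty acid and triglyceride synthesis 2 fell in KO, Thrsp and Me1 (camera adjusted p = 0.0117, and adjusted p = 0.941 with an estimated correlation). In the amino acid and fatty acid lists KO_1 did not follow, with mean log2 deviations from WT of 0.17 and 0.18, beside -0.38 and -0.57 in KO_2 and -0.92 and -1.08 in KO_3.

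Single members of lists that did not pass in KO also changed. The glycogen synthase gene Gys2 fell from 12937 ± 750.2 to 4478 ± 1578, and Igfbp1, a binder of insulin-like growth factor, rose from 630 ± 268 to 8099.7 ± 4776. In the growth hormone axis the cytokine-signalling inhibitor Socs3 rose from 188 ± 84.0 to 1622 ± 1059, while Igf1 fell from 44622 ± 1724 to 28340 ± 3625 and the receptor gene Ghr from 36322 to 17728. The adhesion gene Icam1 rose from 407 ± 46.0 to 1642 ± 251, and the chemokine gene Cxcl9 fell from 227 ± 55.2 to 73.4 ± 9.79. The immediate-early genes Junb and Gadd45b rose, with log2 fold changes of 2.24 and 3.29. The mean log2 deviation of the immediate-early list from WT was -0.06 in KO_1, 0.92 in KO_2 and 0.98 in KO_3. None of these lists passed by camera, with adjusted p of 0.595 for glucose and glycogen, 0.922 for the growth hormone axis, 0.675 for NF-kB and inflammatory genes and 0.0842 for immediate-early genes.

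WT_1 held 10 genes that were at least 4-fold higher, and at least 30, than in each of the other 8 libraries, and all 10 are annotated as processed pseudogenes whose closest protein-coding gene by shared 25-base words is Rpl7a, a ribosomal protein gene. Their summed level was 6782 in WT_1 and at most 157 elsewhere, while Rpl7a itself was 15261 in WT_1 and between 17716 and 22151 elsewhere. More reads on processed pseudogenes throughout the library are argued against, since 610 others had a median log2 difference of -0.13, and transcription of the copies themselves is argued against because Rpl7a in WT_1 was 0.861 of its level in the lowest other library. The sum of Rpl7a and its copies in WT_1 was 1.06 times the mean of the other 8 libraries and within their range, so a sequence variant in Rpl7a that sends reads to its copies may be the source. Beyond transcription of the copies and such a variant no biological explanation was tested, and the reads needed to see such a variant are not in the table.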
